A study of Mus musculus with 27 samples.

How the data were processed

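RNA from epididymal white adipose tissue of C57BL/6N mice was measured in 27 libraries, 3 for each of 9 groups on normal diet or on sequences of high-fat and normal diet. Libraries were made with a TruSeq RNA kit, per the labels' protocols. Reads were trimmed with Trimmomatic 0.33, aligned to mm10 (GRCm38) with TopHat2 2.0.13 and counted per gene with HTSeq 0.6.0, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so genes overlapping on opposite strands are not separated.

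The deposited counts are raw reads per gene in a table of 43616 rows with 43460 gene names, and the 156 rows that share a name with an earlier row hold identical values, so each name was used once. The deposited FPKM cover 22194 rows. Their values equal the count divided by exonic length and by the library's sum over protein-coding names, a relation read from the deposited values themselves. Libraries held 26479773 to 32728594 counts, and TMM factors ran from 0.814 (maintenance library 3) to 1.11 (loss library 3). Between replicates the spread exceeded counting noise, with a chi-square per degree of freedom of 12.0 to 537. The annotation used for counting is not given in the sources used here. Positions were joined by the gene ID deposited with each name from the GENCODE annotation of GRCm38 and were found for 17684 of the 17821 tested names.

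Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17821 names. All 27 libraries entered one model with a mean per group, scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood test), in R 4.3.3. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. There were 9 comparisons of 2 groups and 2 differences of differences, which take an effect against its own controls in one setting from the same effect in another. Levels are TMM-scaled CPM, and reported log2 fold changes are edgeR's, with the SE obtained from the fold change and its test statistic. Library levels and within-set medians use log2 CPM with a prior count of 2. The log2 fold changes of genes with libraries at 0 depend on the prior count, so the size of those given, as for Ucp1 and the immunoglobulin segments, is uncertain.

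In each comparison 41 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM, adjusted over the lists. They cover adipocyte and fat-pad markers, metabolic pathways, immune and stromal cell markers, signalling and stress pathways, other tissues and measures of RNA quality. Markers were read as transcripts of whole tissue, not as cell numbers. Over all comparisons they gave 183 calls with the preset correlation, 0 with an estimated correlation (smallest adjusted p 0.224) and 59 with fry, limma's rotation test. The numbers of list members called are given over all genes and adjusted over the list alone.

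The comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. By that rule a comparison names up to 6 genes per direction with the largest fold changes. They must be called, have groups that do not overlap in CPM and a mean of at least 5 CPM in the higher group, and predicted genes were passed over. It also names the 3 members of each described list with the smallest adjusted p, and 10 markers in every comparison. The text uses the stabler of these, some genes the rule names are not reported here, and gives the library where leaving 1 out ended a call. The alternatives were RLE scaling, no filter, DESeq2 1.42.0, a model of the compared groups only, an adjusted p under 0.01 for the overlaps, each library left out in turn, and limma on the authors' FPKM as log2(FPKM + 1) and log2(FPKM + 0.1). Replicate number as a block was also run, although correlations between like-numbered replicates ran from -0.181 to 0.378 and in 0 of 9 comparisons were all above 0.1, so no pairing was used. Where a left-out library leaves 2 in a group, the spread is pooled over all groups.

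Other choices were made after the data were seen. Libraries were divided at 1000 CPM of Lars2, whose locus carries a sequence like ribosomal RNA, into a high set of 15 and a low set of 12. The set was added as a model term, and each set was fitted alone. Where a set holds 1 library of a group, that library is assumed to vary like the others. Maintenance library 3 was left out of every fit, as were maintenance library 3, loss library 1 and control12 library 3 together. The 4 lists of liver, efferent duct, sperm and ribosomal RNA transcripts were added then too. No library was left out of the reported values. The first 4 principal components of the libraries held 33.7%, 12.9%, 11.0% and 8.79% of the variance.

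The code was tested on simulated data made from the means and library sizes of the 17821 genes, with 200 changed. For gain8 against control8 edgeR recovered 10%, 38%, 62% and 80% of genes changed 1.5, 2, 4 and 8-fold, with 3 of 17621 unchanged genes called. For the difference between loss and gain8 it recovered 2%, 8%, 58% and 72%, with 1 called. A cell cycle list raised 2-fold was called, together with 1 other of the 41 lists. Shared controls were simulated in 20 draws. Other splits of the libraries were counted, all 10 for each comparison of 6 libraries, and 50 drawn at random for 12 or 9 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.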

Results

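Transcripts of epididymal white adipose tissue, the visceral fat pad beside the testis, were counted in C57BL/6N mice carried through a cycle of weight gain, loss and regain. The 27 libraries formed 9 groups of 3. The initial group was taken at 5 weeks of age. The groups control8, control12 and control16 had normal diet for 8, 12 and 16 weeks and were 13, 17 and 21 weeks old. The gain8 group had 8 weeks of a high-fat diet with 60% of its energy from fat. The loss group had those 8 weeks and then 4 weeks of normal diet, and the maintenance group had 8 weeks of each. The gain4 group had the high-fat diet only for the last 4 of 16 weeks. The regain group had 8 weeks of high-fat diet, 4 weeks of normal diet and 4 further weeks of high-fat diet. Libraries held 26479773 to 32728594 counts, and 17821 gene names were tested. Levels below are TMM-scaled CPM, counts relative to library size, as mean ± SD with n = 3, and changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values. The labels number the replicates but do not say that each is a separate animal, so p-values measure the spread between these samples. Exact permutation of 3 against 3 libraries cannot go below p = 0.1.

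Several libraries stood apart from their groups. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was counted at 1324 to 4100 CPM in 15 libraries and at 97.4 to 212 CPM in the 12 others, and every group except initial held libraries of both kinds. These are called the high and the low set, and for some of the lists below medians within each set are given. Summed over 16 liver genes, maintenance library 3 held 10174 CPM, the 3 control8 libraries 111, 173 and 143 CPM, and no other library more than 52.0 CPM. Genes of the efferent duct and ciliated epithelium summed to 322 CPM in control12 library 3, 195 in control8 library 2 and 25.0 in control8 library 3. Sperm transcripts reached 86.3 CPM in gain8 library 2, 69.0 in control12 library 3 and 63.8 in maintenance library 3. Maintenance library 3, loss library 1 and control12 library 3 were also taken out of every fit as an alternative chosen after the data were seen.

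The first comparison asks what 8 weeks of high-fat diet did to the fat pad at 13 weeks of age. Lep, which encodes the satiety hormone leptin, rose from 828 ± 119 to 5400.3 ± 1089 CPM (2.71 ± 0.68, adjusted p = 0.00744). Trem2, the lipid receptor of lipid-associated macrophages, rose from 11.3 ± 2.91 to 203 ± 74.5 CPM (4.17 ± 0.72, adjusted p = 0.000486). Of 22 macrophage markers 20 rose and none fell, among them Slc37a2, a sugar-phosphate carrier (3.75 ± 0.54), Mpeg1, which encodes perforin-2 (2.87 ± 0.48), Cd68 (2.84 ± 0.49), Emr1 encoding F4/80 (2.35 ± 0.40) and Itgax encoding CD11c (3.40 ± 0.63). Of 30 cell cycle genes 29 rose, with Birc5, the mitotic protein survivin, at 14.5 ± 5.93 against 2.01 ± 0.201 CPM (2.85 ± 0.36, adjusted p = 9.3e-05), and with Ube2c (2.24 ± 0.29) and the kinetochore motor Cenpe (2.49 ± 0.37). Against this, Pck1, the glyceroneogenic enzyme, fell by 2.15 ± 0.59 and the insulin receptor gene Insr fell by 1.15 ± 0.18. The list tests (camera) called both lists, with adjusted p = 0.403 for macrophage and 0.388 for cell cycle with an estimated correlation.

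Lipid-associated macrophage genes rose in 18 of 22 cases, with galectin-3 (Lgals3, 3.39 ± 0.46), the lipid droplet coat gene Plin2 (2.25 ± 0.30) and lysosomal acid lipase (Lipa, 2.53 ± 0.37). 21 of 27 lysosome genes rose, including Gusb (2.19 ± 0.25), Hexa (1.51 ± 0.20) and the proton pump subunit Atp6v1b2 (1.65 ± 0.24). Both lists had adjusted p = 0.388 with an estimated correlation. Of 28 cytokine and chemokine genes 15 rose and 1 fell, with the interleukin-1 antagonist Il1rn (4.70 ± 0.85) and the monocyte attractant Ccl2 (2.80 ± 0.51), and with adjusted p = 0.403 with an estimated correlation. Among 11 genes of MHC class II presentation 7 rose, such as H2-DMb1 (2.18 ± 0.31) and Ctss (2.72 ± 0.49), and among 37 matrix genes 13 rose and 2 fell, with Col6a2 (1.95 ± 0.36) and the protease inhibitor Timp1 (3.49 ± 0.62) among those that rose. Their adjusted p with an estimated correlation were 0.432 and 0.663. Of 15 resident macrophage markers 5 fell, among them the chemokine Ccl24, which fell by 1.89 ± 0.44, and Cd209f, which fell by 1.70 ± 0.40 (list adjusted p = 0.681 with an estimated correlation). Their median on mean log2 CPM was -0.84 over all libraries, -0.46 without gain8 library 2 and 0.05 in the high set. Circadian clock genes fell in 6 of 18 cases, the repressor Nr1d1 by a drop from 171 ± 35.3 to 36.8 ± 8.21 CPM (-2.21 ± 0.37), and 5 of 16 insulin signalling genes fell (adjusted p = 0.403 for each with an estimated correlation). Single genes also passed in lists kept to watch for other tissue and RNA quality. Of 13 mesothelium genes 3 fell (median -2.55), of 13 mitochondrial transcripts 3 fell (-0.72) and of 30 ribosomal protein genes 1 rose (0.46), with adjusted p = 0.706, 0.706 and 0.804 with an estimated correlation, and of 7 lymph node genes 1 fell (-1.65), a list that camera did not call. Adipoq, the adiponectin gene, was at 2086 ± 357 CPM in gain8 against 3256 ± 382 (adjusted p = 0.302) and the desaturase gene Scd1 at 16632 ± 6774 against 51214 ± 11423 (adjusted p = 0.0617).

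In total 3833 genes passed an adjusted p of 0.05 in gain8, 2136 higher and 1697 lower, and 1231 and 1040 of them by at least 2-fold. Largest among the rises were Gpr50, an orphan receptor related to the melatonin receptors (114 ± 71.2 CPM in gain8 against 0.218 ± 0.266 in control8), Tph2, a tryptophan hydroxylase (255 ± 92.6 CPM in gain8 against 0.725 ± 0.200 in control8), the integrin Itgad (45.2 ± 18.05 CPM in gain8 against 0.380 ± 0.0638 in control8) and the ubiquitin-like Ubd (293 ± 87.4 CPM in gain8 against 3.24 ± 0.633 in control8). By deposited gene ID, the GENCODE annotation of GRCm38 places ENSMUSG00000059201 (Lep) on chromosome 6, 29060220 to 29073877, ENSMUSG00000023992 (Trem2) on chromosome 17, 48346401 to 48354147, and ENSMUSG00000056380 (Gpr50) on chromosome X, 71663667 to 71669257. Among the largest falls was that of Kap, a kidney and reproductive tract gene, at 8.25 ± 9.27 CPM in control8 and 0 in gain8. Without control8 library 2, which held efferent duct transcripts, the calls of Cdh16 (-6.50), Dcdc2a (-5.73), Cldn2 (-5.72), Adcy8 (-5.51) and Hnf4a (-5.18) ended. Adjusted over the list alone, 20 macrophage and 29 cell cycle genes passed. The macrophage median on mean log2 CPM was 1.81 over all libraries, 1.86 in the high set (1 library of each group) and 1.86 in the low set, and that of the cell cycle genes 1.95, 1.61 and 2.13. Without gain8 library 2 the count was 2137 and without gain8 library 3 it was 2365, while a fit of these 6 libraries only called 6000. The call of Pck1 ended without gain8 library 2 (-2.06) or gain8 library 3 (-2.11), and that of Col1a1, a collagen gene at 860.1 ± 139.6 against 365 ± 138 CPM, without control8 library 3 (1.03).

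**Figure D1:**
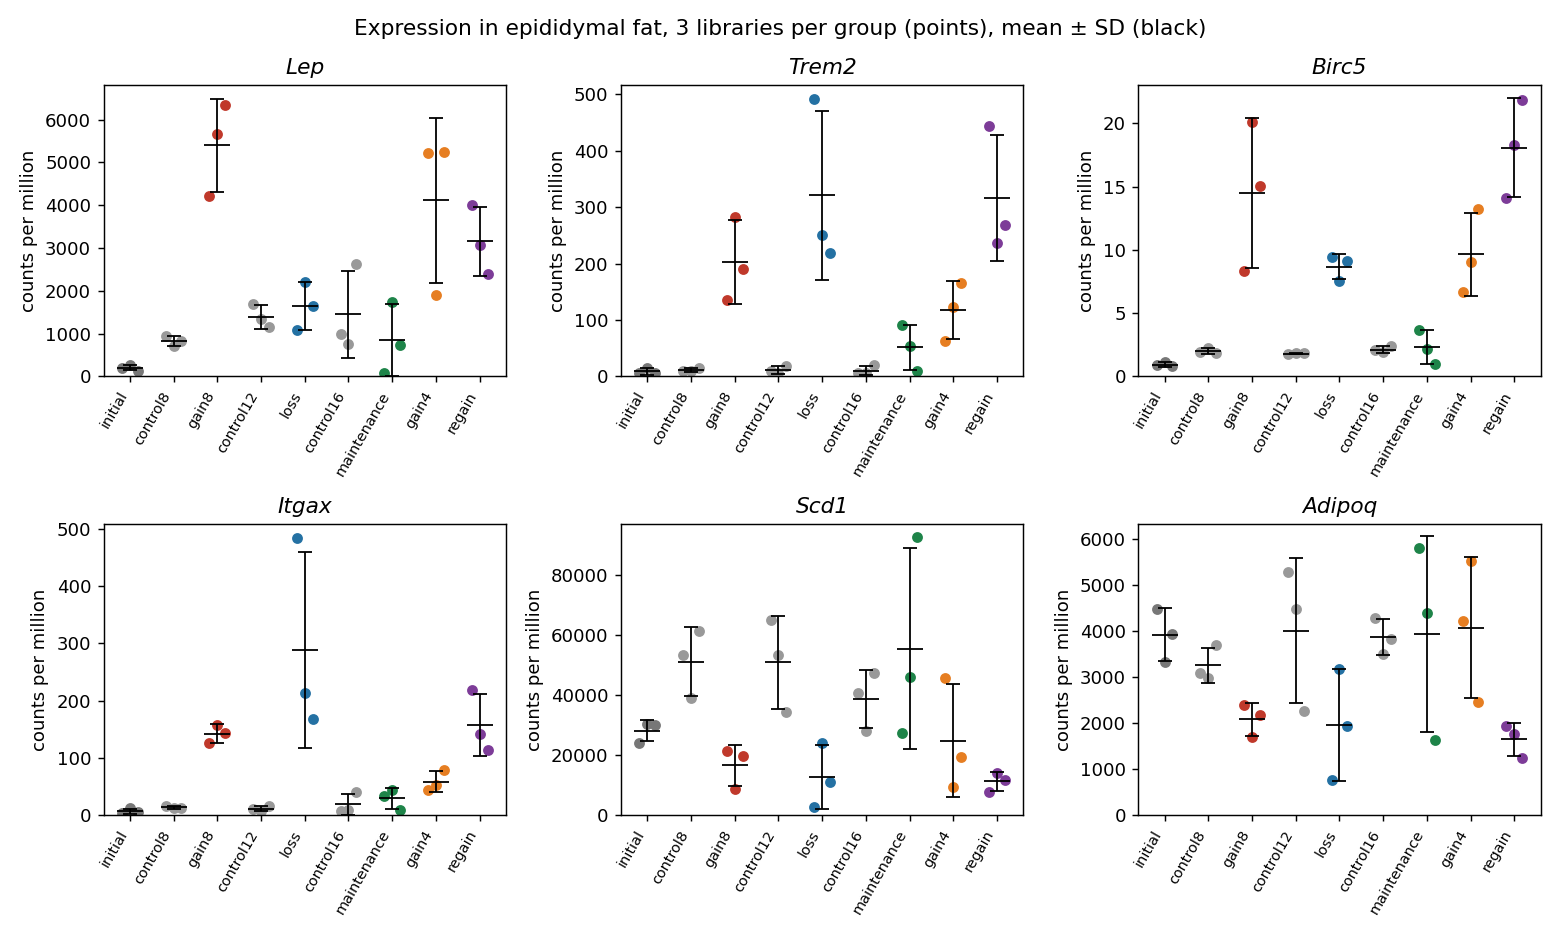
CPM of Lep, Trem2, Birc5, Itgax, Scd1 and Adipoq in each of the 27 libraries (points) with group mean and SD (bars), one panel per gene and the 9 groups along the horizontal axis. Trem2 averaged 203 ± 74.5 CPM in gain8, 321 ± 149 in loss, 316 ± 112 in regain and 118 ± 51.7 in gain4, against 11.3 ± 2.91 in control8.

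Whether the fat pad still differed 4 weeks after the return to normal diet was read from loss against control12. Trem2 stood at 321 ± 149 CPM against 11.2 ± 6.68 (4.83 ± 0.74, adjusted p = 0.000145), while Lep, at 1649 ± 565 against 1391 ± 276 CPM, did not differ beyond the spread (adjusted p = 0.818). Of 22 macrophage markers 19 rose, with Itgax at 289 ± 172 against 11.3 ± 4.72 CPM (4.67 ± 0.67, adjusted p = 8.8e-05) and Cd84 (3.61 ± 0.49), and 17 of 22 lipid-associated macrophage genes rose and 1 fell, with the protease Ctsk (3.98 ± 0.45), Lipa (3.01 ± 0.37), the macrophage elastase Mmp12 (7.37 ± 1.03) and Gpnmb (6.19 ± 0.87). With an estimated correlation these lists had adjusted p = 0.291 and adjusted p = 0.224. Cell cycle genes rose in 28 of 30 cases, among them the sliding clamp Pcna (1.81 ± 0.26), Mcm5 (2.40 ± 0.36) and Birc5 (2.27 ± 0.36), as did 22 of 27 lysosome genes and 13 of 28 cytokine and chemokine genes, of which 1 fell (adjusted p = 0.291 for each of the 3 lists with an estimated correlation). The lysosome median on mean log2 CPM was 1.05, and 0.70 without loss library 1.

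Adipocyte identity genes fell in 6 of 20 cases (9 adjusted over the list alone), with adipsin (Cfd) at 867 ± 551 against 5204 ± 971 CPM (-2.59 ± 0.68), and 8 of 20 genes of branched-chain amino acid breakdown fell, such as Ivd, which fell by 1.12 ± 0.25, and Pccb, which fell by 1.07 ± 0.25. The list adjusted p with an estimated correlation were 0.469 and 0.494. Insulin signalling genes fell in 7 of 16 cases and rose in 1, the kinase gene Akt2 falling by 0.94 ± 0.19 (adjusted p = 0.291 with an estimated correlation). Of the 13 transcripts of the mitochondrial genome 9 fell, mt-Nd4 from 4444 ± 1619 to 1685 ± 514 CPM (list adjusted p = 0.357 with an estimated correlation). Of 8 red-cell genes 7 fell, and 8 of 20 immediate early and heat shock genes rose, with Egr2 at 50.5 ± 33.99 against 2.11 ± 0.853 CPM and Atf3 at 212 ± 123 against 9.59 ± 2.29 (adjusted p = 0.443 for both lists with an estimated correlation). Cd163, a scavenger receptor of resident macrophages, fell by 2.53 ± 0.49, and 5 of 15 resident macrophage markers fell and 1 rose (adjusted p = 0.686 with an estimated correlation). Of 13 mesothelium genes 2 and of 10 epididymis and sperm genes 2 fell (adjusted p = 0.686 and 0.559 with an estimated correlation). Leaving out loss library 1 took the median on mean log2 CPM from -0.93 to -0.43 for adipocyte identity, from -0.82 to -0.48 for branched-chain amino acid breakdown, from 0.43 to 0.25 for immediate early and heat shock and from -1.97 to -0.66 for mesothelium genes, which were at 0.11 with the 3 libraries out. Leaving out loss library 2 took the immediate early and heat shock median to 0.71. The epididymis and sperm median went from -2.11 to -0.77 without control12 library 3 and to -3.18 without control12 library 2.

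The test called 3564 genes in loss, 2096 higher and 1468 lower, of which 1212 and 1045 changed by at least 2-fold. The split was 76.4% higher on log2(FPKM + 1) against 58.8% on counts. Adjusted over the list alone, 21 macrophage, 29 cell cycle and 13 mitochondrial transcripts passed. Median macrophage change on mean log2 CPM was 2.19 over all libraries, 2.48 in the high set, 1.57 in the low set (1 library of each group) and 1.87 with the 3 libraries out, and for cell cycle genes 1.5, 1.73, 0.92 and 1.25. Among the largest falls, Prom2 (-2.74), Elf3 (-2.38) and Dsp (-2.11) lost their calls without control12 library 3, where efferent duct transcripts lay. The count was 1206 without loss library 1, 2368 without control12 library 3, 1490 with the 3 libraries out and 765 in a fit of these 6 libraries only, and the call of Cfd ended without loss library 1 (-2.14).

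Whether the diet effect differed between gain8 and loss was tested as the difference of their differences from controls. Leptin mRNA, which rose in gain8 and not in loss, gave a difference of -2.46 ± 0.91 (adjusted p = 0.626). Trem2 differed by 0.66 ± 0.90 (adjusted p = 0.963) and Itgax by 1.27 ± 0.83 (adjusted p = 0.860). Of 10 mast cell genes none passed over all genes and 7 passed adjusted over the list alone, with the protease Mcpt4 at 3.80 ± 1.05 and Cma1 at 3.74 ± 1.09, and of 18 clock genes none passed, with Nr1d1 at 1.52 ± 0.499. Loss library 1 carried much of the mast cell difference: without it Mcpt4 was at 2.36, Cma1 at 2.20 and the list median on mean log2 CPM at 1.77 against 2.77. Itgax was then at 0.67 and Trem2 at 0.22, and Trem2 ranged up to 1.24 without control12 library 3, while Nr1d1 was at 1.01 without loss library 2. Camera called both lists, with adjusted p = 0.655 for each with an estimated correlation. edgeR called 0 genes, with 1231 at an unadjusted p under 0.05 and a smallest adjusted p of 0.257, and DESeq2 called 32. Leaving out loss library 2 gave 11 genes. In simulated data for this contrast, 58% of genes changed 4-fold and 8% of those changed 2-fold were recovered. That simulation changed 200 genes and held no library standing apart from its group, so these shares need not hold for the measured libraries.

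Maintenance against control16 asks what remained 8 weeks after the return to normal diet. Emr1 was at 79.4 ± 36.4 CPM in maintenance and 77.1 ± 4.44 in control16 (adjusted p = 0.962), Lep at 853 ± 839 against 1455 ± 1019.5 (adjusted p = 0.520) and Adipoq at 3943 ± 2126 against 3869.6 ± 387 (adjusted p = 0.978). Trem2 was at 51.6 ± 40.5 against 10.4 ± 7.89 CPM (2.31 ± 0.67, adjusted p = 0.0772) and Gpnmb at 189 ± 133 against 36.3 ± 16.1 (2.38 ± 0.73, adjusted p = 0.0889). Of 22 lipid-associated macrophage genes none passed over all genes and 7 were higher adjusted over the list alone (list adjusted p = 0.595 with an estimated correlation). Their median on mean log2 CPM was 0.78, and 0.38, 0.44, 0.48 and 0.43 without control16 library 1, control16 library 2, maintenance library 1 and maintenance library 2. The median without maintenance library 3 is not given here. On log2 CPM the list averaged 7.003, 6.79 and 5.98 in maintenance libraries 1, 2 and 3, against 5.76 ± 0.534 in control16. The macrophage list averaged 6.501, 5.94 and 4.56, against 5.59 ± 0.133. Maintenance library 3 was thus the lowest of its group for both lists. The group values of Emr1 and Trem2 therefore do not tell a return to control levels from the part of that library. Of 37 matrix genes none passed over all genes and 10 were lower adjusted over the list alone, with fibrillin-1 (Fbn1) at 85.4 ± 31.8 against 339 ± 95.98 CPM and elastin (Eln) at 65.7 ± 16.1 against 207 ± 45.3 (list adjusted p = 0.595 with an estimated correlation).

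Adjusted over the list alone, 14 of 19 lipogenesis, 17 of 23 cholesterol synthesis, 18 of 20 citrate cycle, 42 of 44 oxidative phosphorylation, 7 of 12 thermogenic and 30 of 30 ribosomal protein genes were higher in maintenance, and none passed over all genes. Each of these lists had adjusted p = 0.595 with an estimated correlation. The lipid gene levels came from 1 library: Acly, the enzyme making cytosolic acetyl-CoA, was at 10955 CPM in maintenance library 3 and at 116 and 137 in the other 2, and Fasn, the fatty acid synthase gene, at 29308, 401 and 758. The same library held liver transcripts, with albumin (Alb) at 5226 CPM against 14.6 and 13.3. On mean log2 CPM the lipogenesis median was 1.19 over all libraries, 3.70 in the high set, which holds that library, -0.15 in the low set and -0.27 with the 3 libraries out. The matrix median was -0.66, -0.81, -0.85 and -0.69, that of ribosomal proteins 0.64, 0.30, 0.84 and 0.77. Over all libraries and with the 3 out, the medians were 0.87 and -0.05 for cholesterol synthesis, 0.59 and 0.21 for citrate cycle, 0.69 and 0.40 for oxidative phosphorylation, and 1.01 and 0.20 for thermogenic genes. Without maintenance library 1 the ribosomal protein median was 0.34 and that of cholesterol synthesis 1.33, and without maintenance library 2 that of lipogenesis was 1.83. edgeR called 0 genes, with 3633 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0508, and DESeq2 called 824. Scaling by relative log expression (RLE) gave 149, no filter on low counts 217, and the count was 2286 without maintenance library 2, 596 without maintenance library 1, 14 without control16 library 3 and 1 without control16 library 2.

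**Figure D2:**
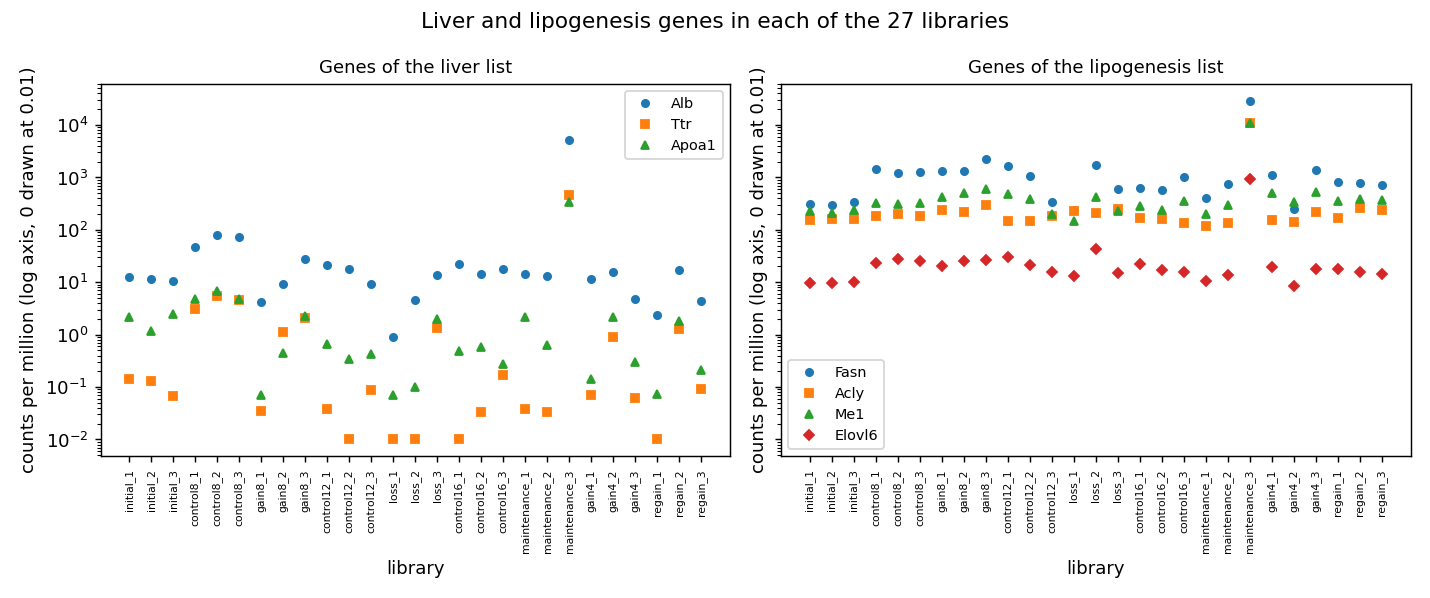
CPM, on a log axis with 0 drawn at 0.01, of 3 liver genes (Alb, Ttr, Apoa1) and 4 lipogenesis genes (Fasn, Acly, Me1, Elovl6) in each of the 27 libraries. Maintenance library 3 reached 5226 CPM for Alb and 29308 CPM for Fasn.

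A first exposure to the high-fat diet over 4 weeks, from 17 to 21 weeks of age, was read from gain4 against control16. Trem2 rose from 10.4 ± 7.89 to 118 ± 51.7 CPM (3.49 ± 0.70, adjusted p = 0.0130) and the acute-phase gene Saa3 from 5.40 ± 3.25 to 229 ± 206 CPM (5.40 ± 1.06, adjusted p = 0.0130). Of 22 lipid-associated macrophage genes 10 rose, with Lgals3 (2.502 ± 0.45) and the proton pump subunit Atp6v0d2 (3.70 ± 0.76), and of 30 cell cycle genes 13 rose, with Birc5 at 9.64 ± 3.30 against 2.12 ± 0.250 CPM (2.18 ± 0.35). With an estimated correlation these lists had adjusted p = 0.530 and adjusted p = 0.722. Fewer members of the general macrophage list passed, 5 of 22, with Cd68 (1.82 ± 0.47) among them, and 6 of 27 lysosome and 4 of 28 cytokine and chemokine genes rose (adjusted p = 0.805 for each with an estimated correlation). Without gain4 library 3 the macrophage median on mean log2 CPM was 0.58 against 0.94. Insr fell by 0.89 ± 0.18, Irs1 fell by 1.41 ± 0.34 and Grb10 fell by 0.85 ± 0.23, the 3 of 16 insulin signalling genes that passed (list adjusted p = 0.722 with an estimated correlation). Fam13a, an adipocyte gene linked to fat distribution, dropped from 636 ± 356 to 74.5 ± 2.25 CPM (-3.09 ± 0.498, adjusted p = 0.00816). Of 30 ribosomal protein genes 1 rose and of 13 mitochondrial transcripts 1 fell (22 and 5 adjusted over the list alone), and of 13 mesothelium genes none passed, with adjusted p = 0.805, 0.808 and 0.808 with an estimated correlation. Their medians on mean log2 CPM were 0.58, -0.60 and -1.53, and 0.29 for ribosomal proteins without gain4 library 2, -0.29 for mitochondrial transcripts without gain4 library 3, and -0.73 and -2.45 for mesothelium without gain4 library 3 and gain4 library 1. Emr1, at 191 ± 126 against 77.1 ± 4.44 CPM, missed the threshold (adjusted p = 0.0508), as did Lep at 4121 ± 1928 against 1455 ± 1019.5 (adjusted p = 0.158).

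In gain4 1037 genes passed, 677 higher and 360 lower, and 340 and 156 changed by at least 2-fold. DESeq2 called 2105, and without the filter on low counts 641 passed with 75.5% higher against 65.3%. Adjusted over the list alone, 17 lipid-associated macrophage, 28 cell cycle and 10 macrophage genes passed. The cell cycle median on mean log2 CPM was 1.003 over all libraries, 0.82 in the high set and 1.23 in the low set, and the lipid-associated macrophage median 1.41, 1.60 and 1.15. Only 3 genes passed without control16 library 1 and 3 without control16 library 2, 485 without gain4 library 2 and 1567 without control16 library 3. A fit of these 6 libraries only called 0 with edgeR.

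Regain against control16 describes the second round of high-fat diet after an earlier gain and loss. Trem2 was at 316 ± 112 against 10.4 ± 7.89 CPM (4.92 ± 0.74, adjusted p = 0.000105), Emr1 at 606 ± 170.2 against 77.1 ± 4.44 (2.97 ± 0.41, adjusted p = 5.6e-05) and Birc5 at 18.1 ± 3.91 against 2.12 ± 0.250 (3.09 ± 0.36, adjusted p = 2.3e-05). Of 30 cell cycle genes 29 rose and of 22 lipid-associated macrophage genes 17 rose, with the thymidine kinase Tk1 (2.89 ± 0.36), Lgals3 (3.51 ± 0.47) and Ctsk (3.22 ± 0.44) among them (adjusted p = 0.234 for both lists with an estimated correlation). Macrophage markers rose in 20 of 22 cases, with the IgG receptor Fcgr1 (3.29 ± 0.45), lysosome genes in 20 of 27 and cytokine and chemokine genes in 14 of 28, with Il1rn (5.24 ± 0.86). Each of these 3 lists had adjusted p = 0.374 with an estimated correlation. Of 11 MHC class II presentation genes 7 and of 22 interferon response genes 11 rose, with Oas1a (1.87 ± 0.36), and their adjusted p with an estimated correlation were 0.565 and 0.825. Of these lists 3 lean on regain library 3, without which the median on mean log2 CPM went from 0.82 to 0.29 for interferon response, from 1.06 to 0.65 for MHC class II presentation and from 1.46 to 0.95 for cytokine and chemokine genes. Without regain library 2 the interferon response median was 1.31. Adipocyte identity genes fell in 9 of 20 cases, Cfd from 5254 ± 1354 to 402 ± 70.3 CPM (-3.71 ± 0.71) and the β3-adrenergic receptor gene Adrb3 from 480.0 ± 115 to 92.2 ± 55.01 CPM (-2.38 ± 0.49) (list adjusted p = 0.781 with an estimated correlation). Pck1 dropped from 4679 ± 1219 to 427 ± 72.4 CPM (-3.45 ± 0.63), Fam13a from 636 ± 356 to 28.3 ± 4.92 (-4.49 ± 0.53) and the transcription factor gene Mycl from 91.5 ± 49.9 to 4.41 ± 1.22 (-4.37 ± 0.81). Of 13 mesothelium genes 1 fell (median -2.45) and of 13 mitochondrial transcripts 5 fell (-0.74), with adjusted p = 0.781 and 0.825 with an estimated correlation, and of 20 immediate early and heat shock genes 4 rose and 1 fell (0.13), a list that camera did not call. Of 30 ribosomal protein genes 1 rose (0.49), with a median on mean log2 CPM of 0.44, and 0.20 without regain library 1. Lep was at 3158 ± 806 against 1455 ± 1019.5 CPM (adjusted p = 0.223).

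The count was 3864 genes, 2219 higher and 1645 lower, with 1360 and 985 changed by at least 2-fold. On log2(FPKM + 1) 69.3% were higher against 57.4% on counts. Of the list members, 20 macrophage and 29 cell cycle genes passed when adjusted over the list alone. The macrophage median on mean log2 CPM was 2.36 over all libraries, 2.24 in the high set and 2.48 in the low set (1 library of each group), and that of cell cycle genes 2.41, 2.61 and 1.96. Without regain library 3 the count was 2303, and the immunoglobulin segment Igkv4-53, at 7.40 ± 12.7 against 0.0114 ± 0.0197 CPM, and Ucp1, the uncoupling protein gene of thermogenic fat at 3.98 ± 6.03 against 0.0453 ± 0.0392 CPM, lost their calls (2.15 and 3.34).

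**Figure D3:**
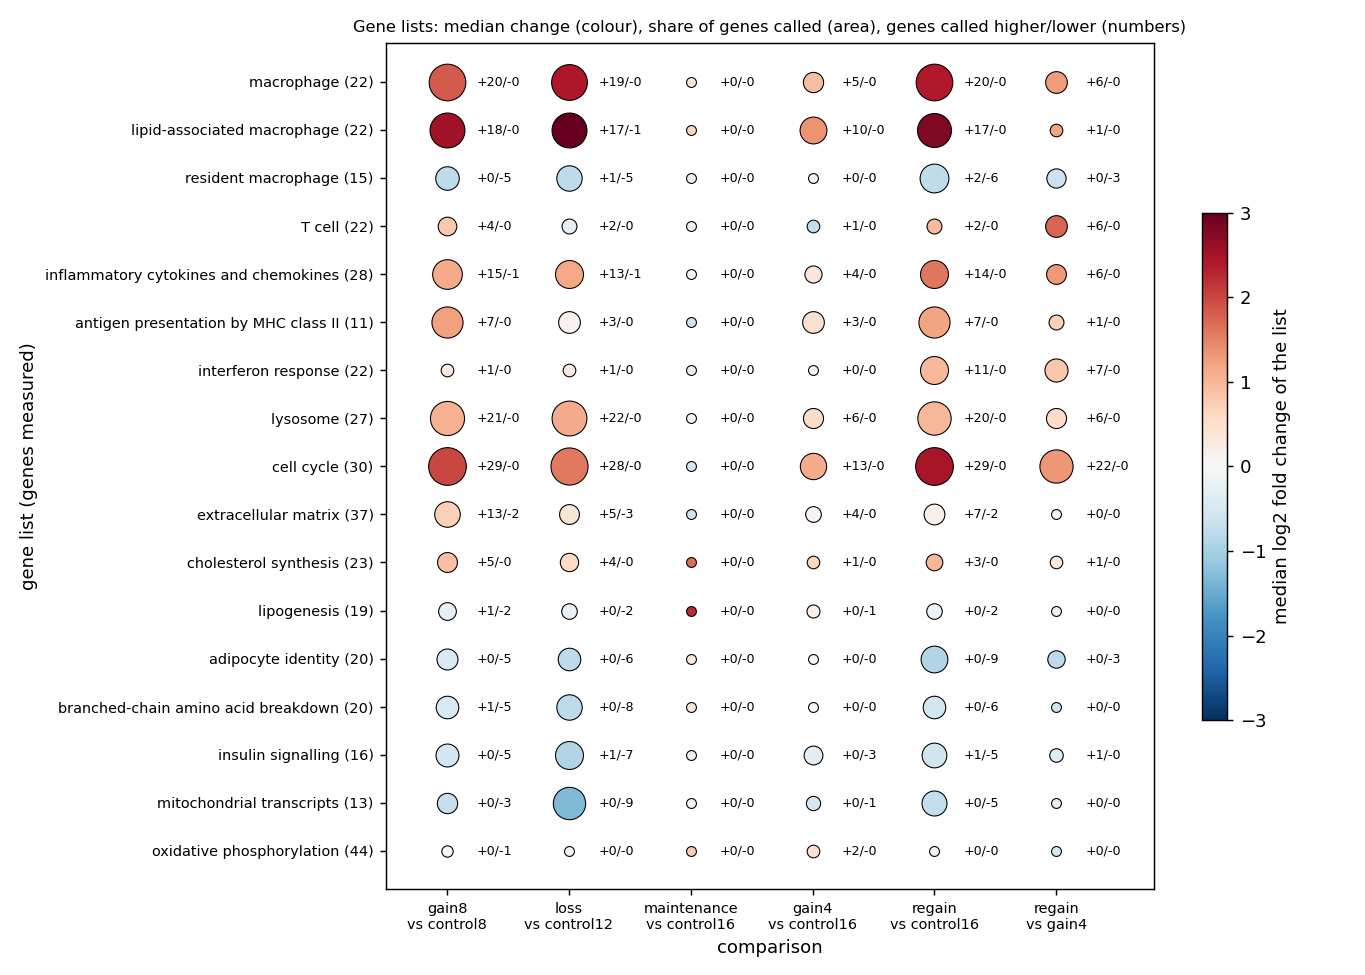
Median log2 fold change of 17 gene lists (vertical axis) in 6 comparisons (horizontal axis), drawn as a colour scale. The cell cycle median was 2.001 in gain8, 1.58 in loss, -0.48 in maintenance, 1.11 in gain4 and 2.47 in regain, each against its controls.

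The direct test of a second against a first 4 weeks of high-fat diet is regain against gain4, both at 21 weeks of age. Regain also had more high-fat diet in total, so history and total exposure are joined in this comparison. Emr1 was at 606 ± 170.2 CPM in regain and 191 ± 126 in gain4 (1.67 ± 0.39, adjusted p = 0.0299), while Trem2, at 316 ± 112 against 118 ± 51.7, and Itgax, at 158 ± 54.3 against 58.1 ± 18.3, missed the threshold (adjusted p = 0.169 and 0.132). Of 30 cell cycle genes 22 rose, with the replication helicase subunits Mcm3 (1.23 ± 0.25) and Mcm2 (1.38 ± 0.28) and the spindle motor Kif11 (1.63 ± 0.37), and of 22 macrophage markers 6 rose, with Fcgr1 (1.86 ± 0.43) and Laptm5 (1.29 ± 0.35). Of 22 T cell genes 6 rose, with Cd4 at 8.06 ± 8.02 against 1.56 ± 0.453 CPM and the co-stimulator Cd28 at 4.78 ± 3.15 against 1.502 ± 0.598. Interferon response genes rose in 7 of 22 cases, with Irgm1 (1.63 ± 0.35) and Zbp1 (2.14 ± 0.5), as did 6 of 28 cytokine and chemokine genes, with Cxcl14 at 20.4 ± 12.3 against 4.32 ± 1.18 CPM, and 6 of 27 lysosome genes. Without regain library 3 the median on mean log2 CPM went from 1.49 to 0.82 for T cell and from 0.75 to 0.36 for interferon response genes, which were at 1.20 without regain library 2. Each of these 6 lists had adjusted p = 0.583 with an estimated correlation. Adipocyte identity genes fell in 3 of 20 cases, resistin (Retn) from 861 ± 570.4 to 210.3 ± 64.6 CPM (-2.03 ± 0.53) and Adrb3 from 331 ± 186 to 92.2 ± 55.01 (-1.84 ± 0.48), with adjusted p = 0.583 with an estimated correlation. None of 13 mesothelium and 8 red-cell genes passed over all genes (7 red-cell genes were lower adjusted over the list alone) and 2 of 20 immediate early and heat shock genes rose, with adjusted p = 0.616, 0.583 and 0.616 with an estimated correlation. The red-cell median on mean log2 CPM was -1.06, and -0.30 without gain4 library 2. Lymph node genes, another list kept to watch for other tissue, averaged 0.534 ± 0.714 in regain and -0.366 ± 0.525 in gain4 on log2 CPM. Adiponectin mRNA was at 1654 ± 359 against 4073 ± 1537 CPM (adjusted p = 0.0772).

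Among the largest rises were the joining chain gene Igj at 69.2 ± 87.8 against 7.12 ± 1.49 CPM and the segment Igkv3-2 at 42.6 ± 72.1 against 0.0578 ± 0.0528. The largest falls included Retnla, from 711 ± 386 to 131 ± 27.9 CPM, the angiotensinogen gene Agt, from 215 ± 183 to 40.8 ± 23.8, and Mogat1, from 13.6 ± 6.28 to 3.28 ± 0.916. In all 978 genes passed, 735 higher and 243 lower, 459 and 127 by at least 2-fold, and the share higher was 75.2%, against 64.2% with DESeq2, which called 2145, and 93.0% on log2(FPKM + 1). Adjusted over the list alone, 28 cell cycle, 20 macrophage and 16 T cell genes passed. Medians on mean log2 CPM over all libraries, in the high set and in the low set were 1.38, 1.69 and 0.73 for cell cycle, 1.28, 1.26 and 1.47 for macrophage, and 1.49, 1.35 and 1.19 for T cell genes. The count was 0 without gain4 library 1 or regain library 3, 1 without gain4 library 2, 2386 without gain4 library 3, 609 without regain library 2 and 0 in an edgeR fit of these 6 libraries only, where the 27-library fit has 4483 genes at an unadjusted p under 0.05. Immunoglobulin segments are near-identical paralogs whose reads can be shared, and without regain library 3 the differences of Igkv3-2, Igj and Cd4 were 4.03, 1.40 and 1.13, none of them called.

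Re-feeding after weight loss was also set against staying on normal diet, as regain against maintenance. Emr1 was at 606 ± 170.2 CPM in regain against 79.4 ± 36.4 (2.93 ± 0.41, adjusted p = 4.8e-05), Trem2 at 316 ± 112 against 51.6 ± 40.5 (2.62 ± 0.67, adjusted p = 0.00647), and the collagen gene Col1a1 at 760.2 ± 228 against 193 ± 9.24 (1.98 ± 0.33, adjusted p = 0.000188). Of 30 cell cycle genes 29 rose, with topoisomerase IIα (Top2a, 3.46 ± 0.41) and Cenpe (3.63 ± 0.39), and adjusted p = 0.281 with an estimated correlation. Macrophage markers rose in 20 of 22 cases, lipid-associated macrophage genes in 16 of 22, MHC class II presentation genes in 9 of 11, with the transactivator Ciita (3.10 ± 0.46), and cytokine and chemokine genes in 16 of 28, with Ccr2 (2.13 ± 0.29). Each of these 4 lists had adjusted p = 0.313 with an estimated correlation. Matrix genes rose in 19 of 37 cases and fell in 1, adipocyte identity genes fell in 14 of 20, with Cfd (-4.72 ± 0.75) and Retn (-3.06 ± 0.55), and genes of branched-chain amino acid breakdown fell in 15 of 20 (adjusted p = 0.426 for each with an estimated correlation). Eosinophil genes rose in 3 of 5 cases, with the eotaxin receptor Ccr3 at 4.02 ± 1.78 against 0.804 ± 0.230 CPM (list adjusted p = 0.313 with an estimated correlation), and the list median on mean log2 CPM went from 1.94 to 1.02 without regain library 1. Of 13 mesothelium genes 5, of 13 mitochondrial transcripts 5 and of 10 epididymis and sperm genes 2 fell, and of 20 immediate early and heat shock genes 6 rose and 1 fell, with adjusted p = 0.498, 0.501, 0.501 and 0.501 with an estimated correlation. The immediate early and heat shock median was 0.22, and 0.34 without maintenance library 1. Lipogenesis genes fell in 16 of 19 cases and oxidative phosphorylation genes in 24 of 44 (adjusted p = 0.501 for each with an estimated correlation), beside the liver transcripts of maintenance library 3. The lipogenesis median on mean log2 CPM was -1.34 over all libraries, -3.77 in the high set, -0.25 in the low set and -0.15 with the 3 libraries out, against 2.34, 3.18, 2.10 and 1.77 for macrophage markers. For oxidative phosphorylation it was -0.66, and -0.39 without maintenance library 3. The test called 4790 genes, 2473 higher and 2317 lower, with 51.6% higher, against 76.7% on log2(FPKM + 1) and 47.7% with RLE, which moved the median of all genes from -0.0747 to -0.109. Among the largest falls, Hgd, Fbp1, Tat and Cyp2a12 are liver genes, and the calls of Fbp1 (-0.97), Tat (-2.30) and Cyp2a12 (-1.001) ended without maintenance library 3. Without regain library 3 the count was 2957, and a fit of these 6 libraries only called 1477.

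Whether the response to the last 4 weeks of high-fat diet depended on history was tested as regain minus maintenance against gain4 minus control16. The lists with most genes called were oxidative phosphorylation, where 28 of 44 genes were lower, with Ndufb10 (-1.64 ± 0.39) and Ndufs7 (-1.68 ± 0.41), and cell cycle, where 19 of 30 were higher, with Cenpf (2.70 ± 0.57) and Cenpe (2.34 ± 0.51). Of 22 T cell genes 3 were higher, with Cd4 (3.14 ± 0.78), and of 20 adipocyte identity genes 5 were lower, with Retn (-2.97 ± 0.74). Each of these 4 lists had adjusted p = 0.530 with an estimated correlation. Trem2 (-0.88 ± 0.89, adjusted p = 0.536) and Itgax (0.80 ± 0.82, adjusted p = 0.537) did not pass. Adjusted over the list alone, 44 oxidative phosphorylation and 26 cell cycle genes passed, and their medians on mean log2 CPM over all libraries, in the high set and in the low set were -1.12, -2.34 and -0.24, and 1.78, 2.51 and 0.86. Of 30 ribosomal protein genes 1 was lower (18 adjusted over the list alone) and of 20 immediate early and heat shock genes 2 were higher (adjusted p = 0.530 for both lists with an estimated correlation). Their medians were -0.74 and 0.80, and -0.48 without gain4 library 2 and -0.49 without maintenance library 1 for the first and 0.5 without maintenance library 3 for the second. edgeR called 1148 genes, 578 higher and 570 lower, and 83.6% were higher on log2(FPKM + 1) against 50.3%, the median of all genes being 0.127 and -0.0249. The count was 1 without maintenance library 3, 0 without control16 library 1, control16 library 2, gain4 library 1, gain4 library 2 or regain library 3, 251 without regain library 2, 694 without maintenance library 1, 2656 without maintenance library 2 and 2914 without gain4 library 3. It was 0 with the replicate block, with the compared groups only and in the low set alone, all with edgeR, and 1645 with the 3 libraries out, so the calls named here hold in some fits and not in others. At an unadjusted p under 0.05 it was 5064, and DESeq2 called 2544.

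Age on normal diet was followed in control8 against initial and control16 against control8. All 3 initial libraries were in the high Lars2 set, and control8 libraries 1 and 3 were in the low set. Age and set are thus partly joined in the first of these comparisons. Liver genes summed to 111, 173 and 143 CPM in the control8 libraries, against 30.5, 20.7 and 27.9 in initial. From 5 to 13 weeks of age Thbs2, a matricellular thrombospondin gene, fell from 432 ± 14.8 to 83.7 ± 18.5 CPM (-2.37 ± 0.43, adjusted p = 0.0150), Rnf125 from 92.1 ± 11.8 to 22.5 ± 4.22 (-2.03 ± 0.36) and Asns, the asparagine synthetase gene, from 178 ± 25.5 to 79.5 ± 22.9 (-1.16 ± 0.26). Col6a6 rose from 17.4 ± 2.03 to 67.97 ± 26.2 CPM (1.96 ± 0.43), Pcbd1 from 2.24 ± 0.883 to 15.6 ± 1.08 (2.80 ± 0.57) and the insulin receptor adaptor Grb14 from 8.55 ± 1.48 to 31.8 ± 10.4 (1.89 ± 0.41). Kap, at 8.25 ± 9.27 CPM in control8 and 0 in initial, was at 18.6 CPM in control8 library 1 and 0.614 in control8 library 2. None of 30 cell cycle genes passed over all genes and 14 were higher adjusted over the list alone (list adjusted p = 0.963 with an estimated correlation). The test called 129 genes, 64 higher and 65 lower, with 2766 at an unadjusted p under 0.05, and DESeq2 called 673. It called 0 without control8 library 1, 1 without initial library 1, 4 without initial library 3 or control8 library 3, 23 without initial library 2, 71 without control8 library 2 and 1937 in a fit of these 6 libraries only. With the Lars2 set as a model term 83 genes were called, and 60 of the 129 kept their call. From 13 to 21 weeks 3 genes passed: RP23-428M4.4 (1.34 ± 0.22), Tbc1d31, which fell by 0.91 ± 0.14, and the deacetylase gene Hdac6, which fell by 0.57 ± 0.09. DESeq2 called 128 and 1538 genes had an unadjusted p under 0.05. The count was 0 without any one of control8 library 1, control8 library 3 or the 3 control16 libraries, and 5 without control8 library 2. Because the counting is not stated to use strand, a clone-named gene such as RP23-428M4.4 is not separated from genes overlapping it on the other strand. Macrophage Emr1 was at 77.1 ± 4.44 CPM in control16 and 69.2 ± 9.21 in control8 (adjusted p = 0.968).

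How far the gain8 profile was shared was measured by genes called in the same direction. Loss shared 1331 higher and 761 lower genes with gain8, where independent lists would share 251 and 139.8, and 3 genes went opposite ways. The log2 fold changes correlated across genes at Pearson r = 0.660, genes not being independent replicates. Regain shared 1447 higher and 771 lower (266 and 157 for independent lists, 5 opposite), gain4 530 higher and 209 lower (81.1 and 34.3), and maintenance 0 with edgeR, which called none of its genes (3633 at an unadjusted p under 0.05), and 115 with DESeq2, which called 824. The number that independent lists would share is not given for the 115. Across genes the edgeR changes in maintenance and gain8 correlated at Pearson r = -0.157 and Spearman 0.0785. Of the genes called in gain8, 54.7% changed in the same direction in maintenance, against 96.1% in loss. These maintenance values include maintenance library 3, which held liver transcripts. Its macrophage genes averaged 1.70 below the mean of all libraries on the log2 scale. The correlations and the 54.7% are not given without that library, so they do not tell its part from that of the group. Taken as lists, the genes higher in gain8 were higher in loss by a median of 0.94 (adjusted p = 0.000179 with an estimated correlation), in regain by 1.05 (adjusted p = 0.000106) and in gain4 by 0.63 (adjusted p = 0.000827), each with an estimated correlation, and in regain over gain4 by 0.45 (adjusted p = 0.0451 with an estimated correlation). These lists come from gain8 and control8, which share no library with the comparisons they were tested in. Their p-values are adjusted over the 2 gain8 lists, higher and lower, of each comparison. They are thus not on the footing of those adjusted over the 41 lists. The genes lower in gain8 were also tested as a list, and both lists in maintenance and in regain against maintenance, and those results are not reported here. The loss overlap was 1022 without loss library 1 and 1393 without gain8 library 2, and 1281 with the 3 libraries out. The gain4 overlap was 3 without control16 library 1 or control16 library 2, 405 without gain4 library 2 and 488 without gain4 library 3. Regain and gain4 shared 482 higher and 243 lower genes against the same control16 libraries (84.3 and 33.2 for independent lists), and 725 in all. Unchanged groups simulated against shared controls shared 0 calls in 20 draws, with a Pearson r of 0.502 against 0.695 observed and a covariance of 0.165 against 0.629. The covariance difference of 0.464 estimates a shared effect only if simulated libraries vary like the measured ones, which was not tested. A regrouping of the 9 libraries that mixes the 3 groups reached a Pearson r of 0.755 with a covariance of 0.478. Another, which keeps the regain libraries together, reached a covariance of 0.545. Such regroupings mix diets, so they do not tell sample structure from a shared effect. The 3 controls cannot be split into 2 sets of at least 2, so the overlap was not tested with separate controls. That overlap was 3 without control16 library 1 or control16 library 2, 408 without gain4 library 2 and 439 without gain4 library 3.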

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

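The differences of differences were planned, and the other tests of this part, the counts over other splits and each test of a single explanation, were written down only after the result was seen, with the rule for regain library 3 revised more than once and the test of the library set in the third pattern replaced once. A test for lymph node tissue in regain library 3 on 5 B cell genes was also run after the values were seen and was not kept.

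Whether the response to the last 4 weeks of high-fat diet differs between mice with and without an earlier gain was tested as regain minus maintenance against gain4 minus control16, and edgeR called 1148 genes (5064 at an unadjusted p under 0.05, 2544 by DESeq2). The immunoglobulin segments Ighv1-9, Igkv2-109, Igkv3-2 and Igkv10-96 differed by 12.04, 9.30, 8.54 and 6.22 on the log2 scale, the serpin Serpina3f by 5.75 and the interferon-induced GTPase Iigp1 by 4.16. The liver genes Uroc1, F9, Mup3, Serpina1c, Itih1 and Apoa2 differed by -9.52, -8.95, -8.75, -8.67, -8.61 and -8.57. Without maintenance library 3 the count was 1, and it was 0 without regain library 3, with the replicate block, with the compared groups only and in the low set alone. With maintenance library 3, loss library 1 and control12 library 3 all out it was 1645, of which 810 are among the 1148. Loss library 1 and control12 library 3 belong to none of the groups compared here. The rise from 1 to 1645 thus came through the shared estimate of spread. Without maintenance library 3 the differences of Uroc1 and Mup3 turned to 1.60 and 0.71. Of 50 regroupings of the 12 libraries 4 gave at least as many genes, the highest other count being 3298, so chance cannot be excluded, and a regrouping with nearly 3 times the real count points to a structure of the samples. These regroupings mix libraries of different diets, so the diet differences themselves enter their counts.

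Other splits were counted for each comparison. The 10 splits of 3 against 3 libraries are too few for a share under 0.05, and the real count with the highest other was 3833 and 0 in gain8 against control8 (1 split as high, the real one included), 3564 and 7 in loss (1), 0 and 353 in maintenance (10, edgeR, with 3633 at an unadjusted p under 0.05 and 824 by DESeq2), 3864 and 0 in regain (1), 1037 and 105 in gain4 (1), 978 and 7 in regain against gain4 (1), 4790 and 2224 in regain against maintenance (1), 129 and 0 in control8 against initial (1) and 3 and 3 in control16 against control8 (2). The 353 genes of a split of maintenance and control16 libraries, where the real one gave 0, point to a structure of the samples. The split with 2224 genes is the low against the high Lars2 set, and so is the one with 105. With the set as a model term regain against maintenance called 5136 genes and gain4 against control16 called 1370. For the difference between loss and gain8 edgeR called 0 genes (1231 at an unadjusted p under 0.05, 32 by DESeq2), which each of the 50 regroupings meets whatever it calls, so their number says nothing about chance. The highest of them called 3535, and these regroupings mix diets too.

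Counts of gene lists with camera's preset correlation were often matched by other splits. The real number, the highest other and the splits as high were 18, 21 and 7 in gain8, 21, 22 and 2 in loss, 19, 18 and 1 in maintenance, 16, 23 and 7 in regain, 17, 14 and 1 in gain4, 20, 18 and 1 in regain against gain4, 23, 24 and 4 in regain against maintenance, 9, 16 and 6 in control8 against initial and 6, 18 and 9 in control16 against control8, of 10 splits each and so too few for a share under 0.05. Of 50 regroupings 34 matched the 14 lists of the difference between loss and gain8 (highest 23) and 19 the 20 lists of the difference between regain and gain4 (highest 25), so chance cannot be excluded for either. The number of lists is therefore not read as support for a comparison. Calls of single genes are given beside each list, but not every comparison has stable ones. In maintenance and in the difference between loss and gain8 edgeR called 0 genes, where DESeq2 called 824 and 32. In regain against gain4 all calls ended in some fits that left out 1 library. The list results there rest on the list medians.

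For shared calls, 100 pairs of splits were counted, and they decide no more than the 10 splits of each comparison. Every other split of the gain8 and control8 libraries called 0 genes with edgeR, where the real one called 3833 (6350 at an unadjusted p under 0.05, 4632 by DESeq2), so pairs with those splits could not share any. The real value and the highest other were 2092 and 0 for gain8 with loss, 2218 and 0 for gain8 with regain and 739 and 40 for gain8 with gain4, each reached in 1 of 100 pairs. For gain8 with maintenance the real 0 is met by all 100 pairs whatever they share (highest 63). For regain with gain4, 3 of 50 regroupings of the 9 libraries shared at least the real 725 calls. Of the other 2, one is the real groups with regain in the place of the controls (750), and one keeps the regain libraries together against the rest divided by Lars2 set (874), so whether chance can be excluded is left open.

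The first pattern weighed is maintenance library 3, where all 16 liver genes had their highest level of the 27 libraries, so RNA from liver in that library is a candidate source. Its lipogenesis genes rose by 134104 CPM in sum against 10149.5 for the liver genes, a ratio of 13.2, but without a liver profile in the tables this does not exclude liver RNA as their source. The median of all genes lay 0.00287 from the other 2 maintenance libraries, which TMM scaling brings about by itself and which decides nothing alone. A factor common to all genes would move the lipogenesis genes equally. They stood 3.61 higher, which argues against such a factor as the source of their rise. A library of another group under this label would need that group to hold such a lipogenesis level. The highest of the 26 other libraries was 0.30 from the mean of all (SD 0.319 over the 26), against 3.43 here. This argues against an exchange within the study as the source of the lipogenesis levels. The pattern was picked for standing above all other libraries, and whether labels were exchanged was not tested otherwise. A sample from outside the study and the state of that animal's fat pad stay open, neither having been tested.

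The second pattern is that genes higher in gain8 were also higher in loss. Loss library 1 alone is argued against by medians of 0.707 in loss library 2 and 0.728 in loss library 3, beside 1.21 in loss library 1, the library set by 2 high and 1 low libraries in each of the 2 groups, with 0.988 within the high set and 0.654 within the low set (1 library of each group), and other tissue in control12 library 3 by 0.858 without it. A lower share of adipocytes with every other cell type kept is argued against because the highest median of 5 lists of other non-immune cell types was -0.52 while that of macrophage genes was 2.42. Whether the earlier high-fat diet or another difference of the loss animals lies behind it stays open, as untested.

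The third pattern is higher cell cycle and macrophage transcripts in regain than in gain4. Regain library 3 alone is argued against by medians of 1.23 for cell cycle genes without it (1.38 with it) and 1.17 for macrophage genes (1.28 with it). Without that library the comparison lost all its calls of single genes, so this rests on the list medians. The library set is argued against for cell cycle genes by a median of 1.24 with the set as a model term, against 1.32 without it (median SE 0.36), where 16 of 30 genes were called against 22, while the medians of 0.730 within the low set and 1.69 within the high set each have only 1 library on one side and decide nothing alone. For T cell genes (0.819 without it, 1.49 with it) and interferon response genes (0.364 and 0.749) the share of regain library 3 cannot be told apart from the group, since 2 libraries remain. The earlier gain and loss, and the longer total time on the high-fat diet, could each give this pattern, and the design joins them, as untested.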

How the results depend on the processing

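The high and low Lars2 sets, leaving maintenance library 3 or the 3 named libraries out of every fit, and the set term were chosen only after the data were seen, and the other alternatives here were planned. For 732 values of named genes, 14577 alternative values were computed. Of these, 11956 kept their side of the threshold, 2016 lost their call, 587 gained one and 18 reversed while called in either fit. A change of direction in a value called in neither fit is counted among the 11956. Modelling the compared groups only kept 488 of 732, and leaving out single libraries kept 4107 of 5160. Below, the count under each alternative that moved it by more than 1.5 times is given, and where nothing else is said the cause was not tested. Models of the compared groups only, of 1 set, or without a library rest on fewer samples.

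For gain8 against control8 the reported 3833 genes became 6000 with the compared groups only, 0 in the high set alone (1 library of each group) and 6490 with the set term and the 3 libraries out. Leaving out single libraries gave 2137 to 3345. For loss against control12 3564 became 765 with the compared groups only, 6300 and 10 in the high and the low set alone, 1490 with the 3 libraries out and 1969 with the set term as well, and 1206 to 4461 without single libraries.

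For maintenance against control16 the 0 of edgeR (3633 genes at an unadjusted p under 0.05) became 149 with RLE, 217 without the filter, 824 with DESeq2, 1 with log2(FPKM + 1), 1 with log2(FPKM + 0.1) and 5199 in the high set alone, and 0 to 2286 without single libraries. For regain against control16 3864 became 734 in the low set alone and 6520 with the set term and the 3 libraries out, and 2303 to 3234 without single libraries.

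For gain4 against control16 1037 became 641 without the filter, 2105 with DESeq2, 0 with the compared groups only and 0 in the low set alone (both edgeR), 5357 in the high set alone, 2056 with maintenance library 3 out, 2583 with the 3 libraries out and 2917 with the set term as well, and 3 to 1567 without single libraries. For regain against gain4 978 became 239 without the filter, 2145 with DESeq2, 0 with the compared groups only, 606 with the replicate block, 5409 and 0 in the high and the low set alone, 1846 with maintenance library 3 out, 2939 with the 3 libraries out and 3331 with the set term as well, and 0 to 2386 without single libraries. Neither comparison holds maintenance library 3, which acts here only through the shared estimate of spread.

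For regain against maintenance 4790 became 1477 with the compared groups only and 2133 in the low set alone, and 2957 to 5033 without single libraries. For control8 against initial 129 became 78 without the filter, 673 with DESeq2, 1937 with the compared groups only, 83 with the set term, 12 in the high set alone, 389 with maintenance library 3 out, 1076 with the 3 libraries out and 923 with the set term as well, and 0 to 71 without single libraries. For control16 against control8 3 became 1 without the filter, 128 with DESeq2, 0 with the compared groups only, 7 with the replicate block, 11 with log2(FPKM + 1), 8 with log2(FPKM + 0.1), 7 with the set term, 0 in either set alone, 31 with maintenance library 3 out, 325 with the 3 libraries out and 561 with the set term as well, and 0 to 5 without single libraries.

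For the difference between loss and gain8 the 0 of edgeR (1231 at an unadjusted p under 0.05) became 32 with DESeq2, 4 with log2(FPKM + 1), 1 with log2(FPKM + 0.1), 8 with the 3 libraries out, 75 with the set term as well and 14 for loss directly against gain8, and 0 to 11 without single libraries. For the difference between regain and gain4 1148 became 337 without the filter, 2544 with DESeq2, 0 with the compared groups only, 0 with the replicate block, 727 with the set term, 6511 and 0 in the high and the low set alone, 1 with maintenance library 3 out, 1645 with the 3 libraries out, maintenance library 3 among them, and 42 with the set term as well, and 0 to 2914 without single libraries. Of the 3 libraries, only maintenance library 3 belongs to the groups of this difference, so the others act through the shared estimate of spread. The 183 list calls over the 11 comparisons became 0 with an estimated correlation and 59 with fry. Fry called 13 in gain8, 13 in loss, 9 in regain and 3 in gain4, each against its controls. It called 18 in regain against maintenance, 2 in regain against gain4 and 1 in the difference between regain and gain4. In maintenance against control16, the difference between loss and gain8 and both comparisons of age it called 0.

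The 2092 calls shared by gain8 and loss became 932 at an adjusted p under 0.01, 672 with the compared groups only, 1281 with the 3 libraries out and 1022 to 2129 without single libraries. The 0 shared by gain8 and maintenance became 10 with RLE, 12 without the filter, 115 with DESeq2 and 0 to 238 without single libraries. The 2218 shared by gain8 and regain became 1091 at an adjusted p under 0.01, 3365 with the 3 libraries out and 4051 with the set term as well. The 739 shared by gain8 and gain4 became 34 at an adjusted p under 0.01, 480 without the filter, 1288 with DESeq2, 0 with the compared groups only, 1370 with maintenance library 3 out, 1776 with the 3 libraries out, 2098 with the set term as well and 3 to 836 without single libraries. The 725 shared by regain and gain4 became 34, 466, 1302, 0, 1376, 1757 and 2135 in that order, and 3 to 970 without single libraries.

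Of named genes, Wfdc2 in loss against control12 turned to 3.14 in the low set alone, 2.30 with the 3 libraries out, 2.36 with the set term as well and 1.86 without control12 library 3, which held duct transcripts, and ran from -7.96 to 1.86 without single libraries. Regain against gain4 turned for Cd163 in the high set alone (0.0165), and regain against maintenance for Peg3 in the high set alone (2.45) and Ucp1 in the low set alone (-1.74). In the difference between regain and gain4, Uroc1 turned to 3.32 in the low set alone, 1.60 without maintenance library 3, 1.59 with the 3 libraries out and 1.91 with the set term as well, Mup3 to 0.38, 0.71, 0.73 and 0.20 (-10.84 to 1.60 and -9.91 to 0.71 without single libraries), and Me1 to 0.32 with the set term and the 3 libraries out. Depth of 26479773 to 32728594 counts leaves genes of a few counts without a usable fold change.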

Other observations

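Mast cell transcripts varied widely between libraries of the same group. The carboxypeptidase gene Cpa3 was at 70.5, 12.1 and 4.66 CPM in the 3 loss libraries, at 62.6, 7.21 and 26.2 in regain and at 24.5, 8.14 and 15.04 in maintenance, against 5.16 ± 1.17 in gain8 and 4.62 ± 0.224 in gain4. The chymase gene Cma1 was at 64.2 CPM in loss library 1 and 67.6 in regain library 1, and 6.08 and 6.59 in the lowest library of each group. Igj, the joining chain of secreted antibodies, was at 170.0 CPM in regain library 3, 28.1 and 9.40 in the other regain libraries, and 28.1 ± 13.9 in control16. Ucp1, the uncoupling protein of thermogenic adipocytes, was at 10.9 CPM in regain library 3 and below 1 CPM in the other 26 libraries.

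Tph2, the tryptophan hydroxylase gene of serotonin synthesis, was at 255 ± 92.6 CPM in gain8, 103 ± 75.9 in regain, 12.7 ± 15.3 in loss and 0.725 ± 0.200 in control8, and in gain4 at 151, 3.10 and 313 CPM in the 3 libraries. Gpr50 followed the same libraries, at 81.5, 3.55 and 147 CPM in gain4. Gain4 library 2 was thus the lowest of its group for both genes.

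Ciliated and duct epithelium transcripts lay in single control libraries. Foxj1, the regulator of motile cilia, was at 45.4 CPM in control12 library 3, 33.5 in control8 library 2 and 2.08 in control8 library 3, and below 1 CPM in the other 24 libraries. Kap, a kidney and reproductive tract gene, was at 18.6 CPM in control8 library 1 and 5.57 in control8 library 3, and below 1 CPM in the other 25. Schwann cell genes averaged 1.77 above the mean of all libraries on the log2 scale in maintenance library 3 and 1.48 in regain library 3. Each of these observations was picked after its values were seen, and none was tested further.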
